A study of Mus musculus with 75 samples.

How the data were processed

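RNA was sequenced from 11 tissues of aged and young C57BL/6 mice, and from the choroid plexus of mice joined in parabiosis, the surgical union of the circulations of a pair of animals. The labels list 75 samples, and 74 libraries were analysed: 63 from tissues and 11 from parabionts. Bone marrow of young mouse 1 has no column in the tissue table, and 1 column of that table (cervical lymph nodes of young mouse 1) matches no listed sample, so neither was analysed here. Aged animals were 22 months old and young animals 3 months old, and mice were perfused with PBS before dissection, per the labels' protocols. RNA was purified with a different kit in each experiment, per the labels' protocols, so values were compared within an experiment and only changes were set side by side.

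Reads were aligned with TopHat to mm9, per the submitters' processing notes; the version of TopHat, the counting tool and the scaling are not given in the sources used here. The deposited unit is a signal: judged from the values, it holds weighted reads per RefSeq transcript divided by one factor per library. The most frequent step in a column is the value worth 1 read, and it ran from 0.527 to 2.19 in the tissue table and from 0.783 to 1.48 in the parabiosis table. Within a tolerance of 0.001 of a step, 77.2% to 84.7% of the values above 0 were whole multiples in tissues and 84.5% to 86.1% in parabionts, so the remaining values hold fractions of reads and whole counts were not recovered. For this reason the count-model test planned first was replaced by its planned substitute for normalised values, limma on log2 values.

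Depth is given as the sum of each column divided by its value worth 1 read. It ran from 187827 to 1134770 reads per library in tissues and from 534663 to 992000 in parabionts. Upper quartiles of the genes above 0 ran from 16.6 to 22.2 in tissues and from 66.0 to 67.8 in parabionts, and genes above 0 numbered 12393 to 15694 and 14666 to 15402. In the parabiosis table no gene exceeded 993 reads, whereas Ttr alone took 29.8% to 34.0% of the reads in choroid plexus of the tissue table.

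There were 25865 transcripts in the tissue table and 21781 in the parabiosis table. Names came from the RefSeq accession for 25311 and 21370 of them, from the current symbol for 366 and 281, and from the symbol in the table for 130 and 91; the other 58 and 39 kept the accession. The transcript with the highest mean was kept for each gene, giving 20680 genes in tissues and 16954 in parabionts; 864 and 822 genes had transcripts that differed. Near-identical copies cannot be told apart: Hba-a1 and Hba-a2, Hbb-b2 and Hbb-bt, H2-Q7 and H2-Q9, H2-T22 and H2-T9, and Pisd-ps1 and Pisd-ps3 share their reads.

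Each comparison was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend and robust settings) on log2 of the value plus a pseudocount, the median over libraries of the smallest value above 0. The pseudocount was 0.0619 for choroid plexus, 0.0407 for the contrast between tissues and 0.0499 for parabionts. A gene was tested where at least as many libraries as the smaller group exceeded 4 times the pseudocount, and was called at a Benjamini-Hochberg adjusted p under 0.05. Each tissue was fitted by itself, and the 4 parabiosis groups were fitted together. The contrast of choroid plexus with the mean of the other 10 tissues used all tissue libraries, with the mouse as a fixed term in the model.

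The genes named in the text follow a rule. In the choroid plexus and parabiosis comparisons these are the 10 higher and 10 lower genes with the largest log2 change among called genes whose libraries do not overlap between groups, and in the other tissues the 5 higher and 5 lower. Where fewer than 5 passed in a direction, the 5 with the smallest p were named and said not to pass. Up to 4 members with the smallest p were named for a described list, and 16 genes of interferon signalling, chemokines, trophic factors and choroid plexus epithelium were always named. Some genes that this rule names are not reported here. Any other gene in the text was chosen after its values were seen.

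There were 39 gene lists, each tested by camera where at least 5 members passed the filter, with a preset correlation of 0.01, two-sided, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks if the members move one way on balance, were run beside it. The type I interferon score is the mean log2 value of the list's members in a library, and groups were compared by a two-sided exact permutation test; with 3 libraries against 3 or 2 its smallest possible p is 0.1. The comparisons, tests, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Those alternatives were quantile normalization, limma without the trend, no filter, a pseudocount 4 times as large, a block for the replicate number, a fit of only the 2 groups compared, leaving out each library in turn, and the other list and score settings. A pseudocount and filter worth 1 read, voom weights, and fits and score comparisons without young mouse 2 were added after the data were seen.

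The share of each organ in a library was estimated by a non-negative fit to the profiles of the other mice, with the 3 lymph node sites pooled. Whether a list stood apart from genes of like expression was tested on 10000 random lists matched in 50 bins of mean expression. Simulated data had 200 changed genes. For choroid plexus the fit recovered 28% of changes of log2 1 and 91% of log2 2 (9921 genes, 0 false calls). For isochronic parabionts shares were 70% and 99% (13557 genes, 7 false calls). They were 1% and 43% for spleen (10826, 2) and 12% and 78% for bone marrow (10393, 8). Real fits tested more genes, so shares may not hold at low values. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 (plots).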

Results

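RNA sequencing gave 63 libraries from 11 tissues of 6 mice, 3 aged and 3 young, and 11 libraries from the choroid plexus of parabionts. Each tissue had 3 aged and 3 young libraries, except bone marrow and cervical lymph nodes, with 2 young libraries, and liver, with 2 aged libraries. The choroid plexus secretes the cerebrospinal fluid and forms the barrier between blood and that fluid. Parabionts were either isochronic, joined to a partner of the same age, or heterochronic, joined to a partner of the other age. There were 3 young isochronic, 3 young heterochronic, 3 old isochronic and 2 old heterochronic libraries. Choroid plexus libraries of the tissue experiment held 570944 to 677123 reads in aged and 534298 to 715159 in young mice. Depth was 746493 to 992000 reads in young isochronic, 675913 to 773403 in young heterochronic, 799608 to 886349 in old isochronic and 534663 to 687909 in old heterochronic parabionts.

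In 8 of the 11 tissues the library of young mouse 2 had a larger fitted share of a second organ than any other library of that tissue. Genes that mark liver, lung or colon by their function in those organs stood high in other tissues of this mouse. The fitted share of lung profile in its spleen library was 65.9%, with Sftpb (NM_147779), a surfactant protein of the lung, at 1471 against 2.117 and 1.963 in the other young spleens. The liver share of its lung library was 62.6%, and Mup3 (NM_001039544), a urinary protein made by the liver, was at 1265 there against 0.881 and 0.808. Its hippocampus library held 61.2% of the lymph node profile, its mesenteric lymph node library 49.3% of colon and its thymus library 45.7% of lymph node. Liver held 37.8% of thymus and cervical lymph nodes 34.0% of hippocampus. The inguinal lymph node share, 31.4% of spleen, is weak evidence: another library of that site held 28.8% of a second organ, and spleens of other mice up to 34.3% of lymph node profile, so the fit hardly separates these organs. The choroid plexus library of the same mouse stood with the others, at 96.1% of its own profile and 1.6% of lung. The inguinal lymph node library of aged mouse 3 held 20.7% of its own profile and high levels of fat cell genes, with Lep (NM_008493), the satiety hormone of fat cells, at 792.1 against 4.462 and 5.094 in the other aged mice.

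**Figure D1:**
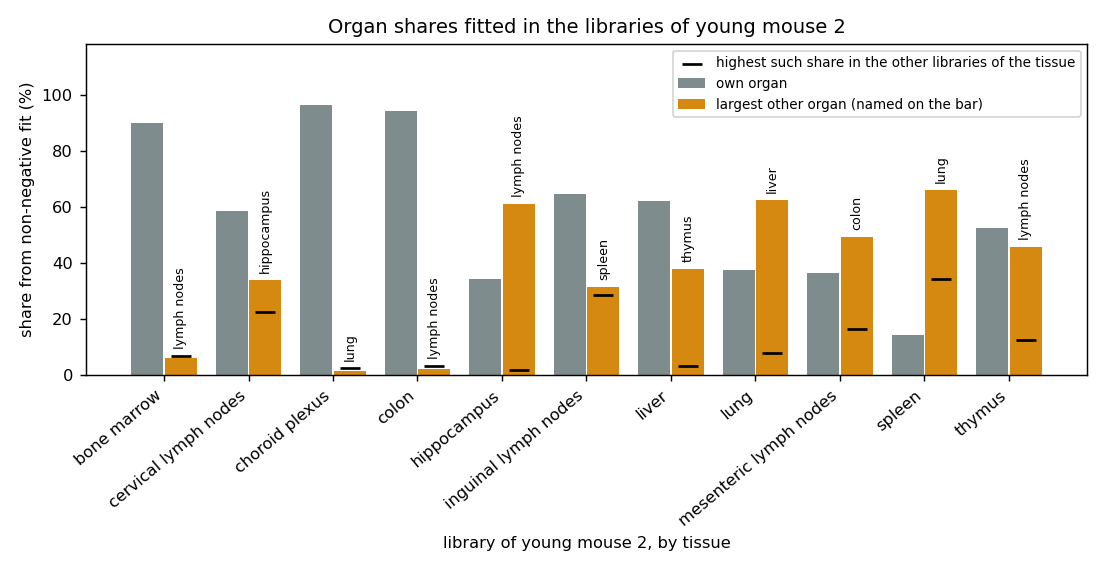
Share of the fitted profile (vertical axis, percent) in each library of young mouse 2 (horizontal axis, by tissue), with a grey bar for its own organ and an orange bar for the largest other organ, named above it. Black ticks give the highest such share in the other libraries of the tissue, which the orange bar passes in 8 of 11 tissues, with 65.9% in spleen and 1.6% in choroid plexus.

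The first comparison asked how age changed the choroid plexus. Genes of the type I interferon response, the antiviral programme that cells switch on after interferon binds its receptor, made up the main group of the higher genes. Isg15, a ubiquitin-like protein conjugated to other proteins in infected cells, Ifit1, which binds viral RNA, Rtp4 and Irf7, the factor that amplifies the response, rose with age. Bst2, which tethers budding virus to the cell surface, and Ifitm3, which blocks viral entry, rose as well. H2-Eb1, a chain of the MHC class II molecule that presents antigen to helper T cells, rose too. Ccnd2, a D-type cyclin that drives entry into the cell cycle, and Ndn, a maternally imprinted gene that restrains growth in neurons, fell.

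With limma, 24 genes were higher and 2 lower in aged choroid plexus among 14227 tested, and 823 had an unadjusted p under 0.05. Isg15 (NM_015783) rose by log2 3.49 (SE 0.577, adjusted p = 0.00481), from 1.88 ± 0.970 to 21.1 ± 8.32 (mean ± SD, n = 3 in each group). Ifit1 (NM_008331) rose from 2.09 ± 0.954 to 19.0 ± 3.17 (log2 3.25, SE 0.572, adjusted p = 0.0089). Rtp4 (NM_023386) rose by log2 3.24 (adjusted p = 0.0137) and Irf7 (NM_016850) by log2 2.90 (SE 0.604, adjusted p = 0.0418; 15.9 ± 8.38 against 1.96 ± 0.565). Bst2 (NM_198095), at 280.9 ± 89.4 against 89.4 ± 20.3, and Ifitm3 (NM_025378), at 144.0 ± 26.6 against 51.3 ± 4.09, rose by log2 1.63 and 1.47 (adjusted p = 4.269e-04 for both). Ifi27l2a (NM_029803), a mitochondrial protein induced by interferon, rose by log2 2.09 (SE 0.343, adjusted p = 0.00644). Ifi27 (log2 0.64), Ly6e (log2 0.94), Shfl (log2 1.63) and Lgals3bp (log2 1.12), which also respond to interferon, passed at adjusted p between 6.266e-04 and 0.0379. Ccnd2 (NM_009829) fell from 468.2 ± 22.6 to 229.3 ± 22.2 (log2 -1.03, adjusted p = 4.269e-04), and Ndn (NM_010882) fell from 26.4 ± 3.50 to 4.42 ± 0.729 (log2 -2.57, adjusted p = 0.00414). Below the threshold in the lower direction, Whrn, a scaffold of sensory cilia, was at log2 -0.80 (NM_001008791, adjusted p = 0.0579), Sparc, a collagen-binding matrix protein, at log2 -0.61 (NM_009242, adjusted p = 0.0665), and Calr, a chaperone of the endoplasmic reticulum, at log2 -0.44 (NM_007591, adjusted p = 0.0688).

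Other genes that rose have no place in the interferon response. Tlx2 (NM_009392), a homeobox factor of the enteric nervous system, was listed at 0 in all 3 young libraries and stood at 35.9, 29.3 and 17.9 in the aged ones (adjusted p = 0.0033). Sult1c1 (NM_018751), a cytosolic sulfotransferase, stood at 29.5, 44.0 and 41.4 against 0, 1.38 and 0 (adjusted p = 0.00112). Cox8b (NM_007751), a subunit of cytochrome oxidase found in muscle and brown fat, rose from 91.8 ± 36.5 to 327.3 ± 37.8 (log2 1.91, adjusted p = 0.00105). Pisd-ps1 and Pisd-ps3 (NR_003517 and NR_003518), pseudogenes of a phosphatidylserine decarboxylase, share their reads. Together they stood at 97.5 ± 4.60 against 22.5 ± 1.44 (log2 2.11, SE 0.223, adjusted p = 1.604e-05), and Pisd, the gene they resemble, rose by log2 1.22 (adjusted p = 0.0416). Mdk (NM_010784), a heparin-binding growth factor, rose by log2 1.22 (adjusted p = 0.0089), Trf (NM_133977), the iron carrier transferrin, by log2 0.93 (adjusted p = 0.00916), and Apoe (NM_009696), a lipid carrier, by log2 0.48 (adjusted p = 0.0234).

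Of 27 type I interferon response genes tested, 25 lay above 0, with a median of log2 2.02; 7 were called, and 12 when adjusted over the list alone (camera adjusted p = 2.230e-19). The adjusted p was 0.0659 with an estimated correlation, and fry gave 0.0183. Ifit3, which binds viral RNA with Ifit1, was at log2 2.37 (adjusted p = 0.627), Oasl2 at log2 3.42 (adjusted p = 0.837) and Usp18, which removes Isg15 from its targets, at log2 1.24 (adjusted p = 0.841), so these 3 did not pass. The genes that load antigen onto MHC class I all lay above 0 (14 of 14, median log2 1.07, 0 called, 4 over the list alone). By camera these genes had adjusted p = 3.102e-06, or 0.306 with an estimated correlation. H2-D1, at 78.5 ± 34.1 against 36.9 ± 5.13, and H2-K1, at 143.0 ± 51.7 against 75.1 ± 11.9, were among them, and H2 copies share reads. MHC class II presentation genes lay above 0 in 7 of 7 (1 called, 4 over the list alone, camera adjusted p = 4.459e-09, or 0.206 with an estimated correlation), and H2-Eb1 (NM_010382) rose from a mean of 17.1 to 48.2 (log2 1.44, adjusted p = 0.0351). The interferon gamma response, the programme that activates macrophages, had a median of log2 1.38 (19 tested, 0 called, 3 over the list alone). For this group camera gave adjusted p = 9.071e-06, or 0.438 with an estimated correlation. Macrophage and microglia markers, which rise where these cells enter or multiply, had a median of log2 1.14 (15 of 17 above 0, 0 called, 0 over the list alone, camera adjusted p = 3.807e-04, or 0.438 with an estimated correlation), led by Lyz2, the lysozyme of myeloid cells (log2 1.06, adjusted p = 0.589). Complement, which tags debris and microbes for uptake, had a median of log2 0.87 (10 of 12 above 0, 0 called, 0 over the list alone). Camera tested the list at adjusted p = 0.00112, or 0.574 with an estimated correlation. Erythroid genes, which mark blood in the tissue, had a median of log2 0.88 (5 of 6 above 0, 0 called, 0 over the list alone, camera adjusted p = 0.0291, or 0.599 with an estimated correlation). Without young 2 that list was not called (median log2 0.74, camera adjusted p = 0.183).

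Clock genes, which set daily rhythm, lay on both sides of 0. Arntl (NM_007489), the activator, stood at 1.28, 0 and 1.12 in aged and at 11.98, 8.28 and 7.53 in young mice (adjusted p = 0.506), and Nr1d2, a repressor, at 67.1 ± 11.3 against 32.4 ± 6.76 (log2 1.06, adjusted p = 0.0959). None of the 17 clock genes was called over all genes. Adjusted over the list alone, 6 were higher and 2 lower (camera adjusted p = 0.00464, or 0.306 with an estimated correlation). The epithelial genes of the choroid plexus, which carry out its transport and secretion, lay on both sides of 0 (8 above, 12 below; median log2 -0.10, camera adjusted p = 0.275). Ttr, the thyroid hormone carrier of the cerebrospinal fluid, was at log2 -0.06 (adjusted p = 0.941), and Kl, the anti-aging hormone klotho, at log2 -0.29 (905.8 ± 111.6 against 1106 ± 92.0; adjusted p = 0.837). Growth and trophic factors had a median of log2 0.02 while camera pointed down (adjusted p = 0.922), and Igf1 was at log2 1.33 (adjusted p = 0.941). Ifnb1, the beta interferon itself, was too low to test, with 1.12 in aged mouse 3 and 0 in the other 5 libraries, as were the chemokines Cxcl10 (3.84 in aged mouse 1 only) and Ccl17. Ccl11 and the neurotrophin Bdnf were listed at 0 in all 6. Icam1, which lets leukocytes attach to endothelium, was at log2 0.32 (adjusted p = 0.941).

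The libraries of the groups did not overlap for 1618 genes (11.4%), where 10% is the share by chance. The 26 calls fell to 8, 11 and 9 without aged mouse 1, 2 or 3 and to 15 and 16 without young mouse 1 or 2. Isg15, Ifit1, Rtp4 and Tlx2 were not called when any one of the 3 aged libraries was left out, and limma without a trend called 112 genes, of which 4 were among the 26.

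The next comparison asked whether the age effect in choroid plexus differed from the mean age effect of the other 10 tissues. In the main fit Isg15, Ifit1 and Oas1a, which makes the signal that activates RNase L, had a larger rise in choroid plexus. The fitted difference was log2 3.19 for Isg15 (NM_015783, SE 0.641, adjusted p = 0.00177), 2.99 for Ifit1 (NM_008331, SE 0.596, adjusted p = 0.0016) and 4.34 for Oas1a (NM_145211, adjusted p = 0.0282). For Pisd-ps1 and Pisd-ps3 it was 1.76 (adjusted p = 3.580e-07), for Pisd 1.06 (adjusted p = 0.00366), and for Sult1c1 7.87 (SE 1.08, adjusted p = 4.832e-06). Tlx2 had the largest fitted difference, 9.71 (SE 1.30, adjusted p = 3.051e-06). Crhbp, the carrier that buffers corticotropin-releasing hormone, was at 6.99 (adjusted p = 1.617e-04), and Fsip1 and Kdf1, a sperm sheath and a keratinocyte protein, at 6.87 and 6.52. Among genes with a lower age effect in choroid plexus were Ppp2r2b, a phosphatase subunit (-6.88), Ecel1, a neuronal peptidase (-6.24), Abcc9, a subunit of the potassium channel that senses ATP (-6.21), Klf11 (-5.95) and Isoc2b (-5.93). Most of these values depend on the pseudocount. With one worth 1 read and its filter, Sult1c1 and Tlx2 were at 4.81 and 4.88, Crhbp at 2.47, Kdf1 at 3.19, Oas1a at 1.48, and Ecel1, Abcc9, Klf11 and Isoc2b between -1.65 and -2.50. Of the 5 lower genes, voom called none, and the 1-read setting called Ppp2r2b alone (-2.38, adjusted p = 0.0411). Isg15 and Ifit1 kept their call with 1 read (adjusted p = 0.0411 and 0.0176) but not with voom (0.231 and 0.0862), as did Pisd (0.0313 and 0.0862), and Oas1a and Fsip1 kept it with neither. Tlx2, Sult1c1, Crhbp, Kdf1 and the Pisd pseudogenes kept it with both. Without young mouse 2, Oas1a, Pisd, Fsip1, Kdf1 and Abcc9 lost it. Ifit3 (2.52, adjusted p = 0.0688), Rtp4 (3.30, adjusted p = 0.0841), Irf7 (2.49, adjusted p = 0.365), Bst2 (1.55, adjusted p = 0.326) and Ifitm3 (1.46, adjusted p = 0.227) did not pass.

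In all, 188 genes had a higher and 127 a lower age effect in choroid plexus among 20179 tested, but 3 of the 9 other splits of the mice gave as many, so the count of 315 is not specific to age. With a pseudocount and filter worth 1 read 17 were higher and 6 lower, voom gave 10 and 3 and a fit without young mouse 2 gave 168 and 105. Of 32 type I interferon genes, 30 had a fitted difference above 0 (median log2 1.84, 5 called, 15 over the list alone). Camera gave adjusted p = 1.521e-12, or 0.555 with an estimated correlation.

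The interferon score used all 32 genes (27 tested in choroid plexus) and a pseudocount per tissue, so scales differ. In choroid plexus it was 2.18 ± 0.458 in aged and 0.317 ± 0.119 in young mice (n = 3 in each), a difference of 1.86 (exact permutation p = 0.1, the smallest possible; 0.367 adjusted over the 11 tissues). The difference was 0.94 in cervical lymph nodes (exact p = 0.1), 0.42 in lung (exact p = 0.2), 0.32 in mesenteric lymph nodes (exact p = 0.5), 0.29 in liver (exact p = 0.7), 0.26 in colon (exact p = 0.5) and 0.05 in spleen (exact p = 0.8). It was -0.01 in thymus (exact p = 1), -0.06 in bone marrow (exact p = 0.7), -0.45 in hippocampus (exact p = 1) and -1.01 in inguinal lymph nodes (exact p = 0.1). The hippocampus value rests on young mouse 2, whose library (61.2% lymph node profile) scored 4.15. Without it the difference turned to 1.21, with young libraries at -0.991 and -0.662 and aged ones from 0.099 to 0.693, and the list median was log2 0.90 (0 called, camera adjusted p = 0.0078, or 0.434 with an estimated correlation). The age difference in choroid plexus exceeded that in inguinal lymph nodes by 2.87 (exact permutation p = 0.005; 0.05 adjusted over 10 tissues), that in bone marrow by 1.91 (exact p = 0.035; 0.119 adjusted) and that in thymus by 1.86 (exact p = 0.05; 0.119 adjusted). For the other 7 tissues the difference lay between 0.92 in cervical lymph nodes (exact p = 0.41; 0.41 adjusted) and 2.31 in hippocampus (exact p = 0.195; 0.217 adjusted), and no adjusted p of the 10 was under 0.05. Without young mouse 2 in the other tissue, it ran from 0.65 in hippocampus (exact p = 0.575) to 2.74 in inguinal lymph nodes (exact p = 0.01; 0.1 adjusted). These tests treat tissues of one mouse as independent and assume no age effect in either.

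**Figure D2:**
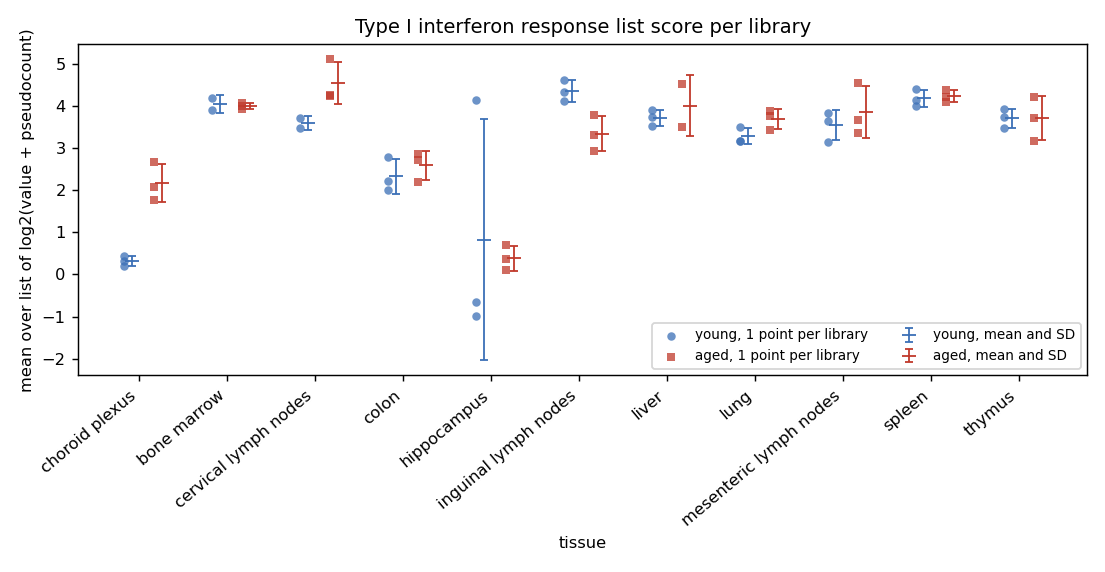
Type I interferon score (mean log2 of value plus pseudocount over the list, vertical axis) by tissue (horizontal axis), with a point per library, young as circles and aged as squares, and bars for group mean and SD. In choroid plexus the 3 aged libraries lie above the 3 young ones, with means of 2.18 and 0.317, and the high young point in hippocampus is young mouse 2 at 4.15.

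In the thymus, which shrinks with age and fills with fat, several genes of fat cells rose. Fasn, the enzyme that builds fatty acids, Acaca, which supplies its substrate, and Elovl6, which lengthens its product, were higher in aged mice. Lipe and Plin1, which govern the release of stored fat, and Adrb3, the adrenergic receptor of fat cells, were higher too. With limma 48 genes were higher and 0 lower among 14886 tested (1755 with unadjusted p under 0.05, voom called 123 higher and 4 lower, and limma without trend 32 higher and 65 lower, 2 of them among the 48), at 187827 to 678609 reads in aged and 376062 to 738576 in young libraries. Fasn (NM_007988) rose from 57.5 ± 15.8 to 498.6 ± 143.3 (log2 3.11, SE 0.261, adjusted p = 2.734e-04). Gpd1 (NM_010271), which makes the backbone of triglycerides, rose by log2 3.57 (adjusted p = 0.00836), Tns4 by 3.30 (adjusted p = 0.0256), Tmem45b by 3.30 (adjusted p = 0.0194) and Adrb3 (NM_013462) by 2.78 (adjusted p = 0.00836). Col1a1, the main collagen chain of connective tissue, rose by log2 1.82 (adjusted p = 0.0498), and Cd163, the haemoglobin scavenger receptor of macrophages, by log2 2.32 (adjusted p = 0.0478). Fat cell genes lay above 0 in 14 of 14 (median log2 1.97, 4 called, 10 over the list alone). For this group camera gave adjusted p = 6.449e-16, or 0.438 with an estimated correlation. Thymocyte genes had a median of log2 -0.30 (0 called, 2 over the list alone, camera adjusted p = 0.0145, or 0.613 with an estimated correlation), with Rag2, the recombinase of developing T cells, at log2 -1.07 (adjusted p = 0.209). Reg3g (log2 -1.67, adjusted p = 0.0735) and Tmem123 (log2 -1.37, adjusted p = 0.0755) stood lower without passing. The library of young mouse 2 held 45.7% of lymph node profile. Without it the thymocyte median was log2 -0.80 (camera adjusted p = 3.941e-08) and 163 genes were called, and without aged 1, aged 3, young 1 or young 3 there were 5, 10, 3 and 21.

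In the spleen, several granule genes of developing neutrophils rose with age. Ngp and Camp, proteins of the secondary granules, and Mpo and Prtn3, enzymes of the primary granules, were higher, as were S100a8 and S100a9, the calcium-binding pair of mature neutrophils. Gzma, a granule protease of killer cells, fell. With limma 9 genes were higher and 2 lower among 14519 tested (1225 with unadjusted p under 0.05), at 365899 to 795491 reads in aged and 423635 to 608755 in young libraries. Ngp (NM_008694) rose from 7.68 ± 4.52 to 227.2 ± 67.3 (log2 5.00, SE 0.407, adjusted p = 4.797e-04), Camp by log2 4.84 (adjusted p = 4.797e-04), Prtn3 by 4.53 (adjusted p = 0.00861) and Mpo by 4.39 (adjusted p = 0.0016). C130026I21Rik (NM_001037909), a gene of the Sp100 family, stood at 70.9 ± 15.1 against 0.4899 ± 0.332 (log2 7.31, adjusted p = 4.797e-04). Gzma (NM_010370) fell by 2.23 on the log2 scale (adjusted p = 0.0152) and Als2cl, a regulator of endosome traffic, by log2 -2.76 (adjusted p = 0.038). Gzmk, a protease of memory killer cells, stood at 10.6, 23.9 and 16.8 and was listed at 0 in the young mice (adjusted p = 0.0662). Neutrophil genes had a median of log2 1.88 (14 of 16 above 0, 6 called, 9 over the list alone). Camera tested the list at adjusted p = 1.159e-14, or 0.189 with an estimated correlation. Plasma cell genes, which serve antibody secretion, had a median of log2 1.12 (11 of 11 above 0, 0 called, 6 over the list alone). By camera these genes had adjusted p = 8.769e-08, or 0.189 with an estimated correlation. Exocrine pancreas genes, of digestive enzymes, had a median of log2 -5.96 (0 called, camera adjusted p = 2.027e-09, or 0.642 with an estimated correlation). Cela2a, an elastase among them, stood at 1586 and 536.9 in young 2 and 3 and at 5.291 or less in the other 4 libraries, so these 2 carry pancreas transcripts. The library of young mouse 2 held 65.9% of lung profile. Without it the pancreas median was log2 -4.20, 21 genes were called, without young 1 there were 36, and without aged 1, 2 or 3 there were 7, 3 and 2.

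In cervical lymph nodes, genes of plasma cells, which secrete antibody, stood higher and those of T cells lower. There (15300 genes tested; 1073 with unadjusted p under 0.05, 388514 to 551742 reads in aged and 384758 to 532327 in young libraries) 2 genes were higher and 1 lower. C130026I21Rik rose to 52.0 ± 7.70 (n = 3) from 0.277 and 0 in the 2 young libraries (limma adjusted p = 0.00941), and Mcpt4 (NM_010779), a chymase of connective tissue mast cells, rose by log2 3.77 (adjusted p = 0.0303). Dapl1 (NM_029723), a gene of naive T cells and epithelia, fell by 4.41 on the log2 scale (SE 0.560, adjusted p = 0.0331), from 69.8 ± 18.9 to 3.63 ± 2.41. Plasma cell genes lay above 0 in 11 of 11 (median log2 2.12, 0 called, 10 over the list alone, camera adjusted p = 1.159e-15, or 0.419 with an estimated correlation), led by Mzb1, which assists antibody assembly, at log2 2.17 (adjusted p = 0.148). T cell genes had a median of log2 -0.85 (0 called, 7 over the list alone, camera adjusted p = 1.113e-09, or 0.419 with an estimated correlation), with Lef1, a factor of naive T cells, at log2 -1.76 (adjusted p = 0.164) and Cd8b1, a chain of the CD8 coreceptor, at log2 -1.79 (adjusted p = 0.18). Type I interferon genes lay above 0 in 31 of 32 (median log2 0.81, 0 called, 0 over the list alone). For this group camera gave adjusted p = 1.113e-09, or 0.44 with an estimated correlation. Bpifa2, a protein of salivary glands, stood at 26170, 70560 and 56.24 in aged 1, 2 and 3 and at 10450 and 60.32 in young 2 and 3, so some libraries carry salivary gland transcripts. The library of young mouse 2 held 34.0% of hippocampus profile. Without it the interferon median was log2 0.51 (camera adjusted p = 0.00579). Without young 3 there were 1351 calls, with a lone young library assumed to vary like the others, and without any one aged library there were 0.

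In mesenteric nodes (14533 tested; 1150 with unadjusted p under 0.05, 357281 to 741196 reads in aged and 466003 to 829554 in young libraries), limma called C130026I21Rik alone, higher by log2 6.09 (SE 0.451, adjusted p = 3.331e-04; 82.0 ± 39.7 against 1.09 ± 0.141). S100a9 was at log2 3.01 (adjusted p = 0.0546) and Sncg, a synuclein of sensory neurons, at log2 2.19 (adjusted p = 0.133). Neutrophil genes, which serve phagocytosis and killing of bacteria, had a median of log2 2.29 (13 of 15 above 0, 0 called, 5 over the list alone). Camera tested the list at adjusted p = 5.721e-09, or 0.23 with an estimated correlation. Colon epithelium genes had a median of log2 -2.07 (0 called, 0 over the list alone, camera adjusted p = 0.0168, or 0.725 with an estimated correlation), and the library of young mouse 2 held 49.3% of colon profile. Without it that list was not called (median log2 0.22, camera adjusted p = 0.241). Exocrine pancreas genes had a median of log2 -4.27 (0 called, camera adjusted p = 4.379e-05, or 0.534 with an estimated correlation) and -5.74 without young mouse 2. They rest on young 3, with Pnlip, the pancreatic lipase, at 3614 there and at 4.682 or less in the other 5. Without young 1 there were 5 calls, without young 2 there were 2, and voom gave 0.

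In inguinal nodes limma called 0 of 14062 genes (591 with unadjusted p under 0.05, smallest adjusted p 0.496, voom 0, limma without trend 53), at 286723 to 413793 reads in aged and 287222 to 547080 in young libraries. C130026I21Rik stood at 41.2 ± 1.29 against 2.36 ± 1.34 (log2 4.32, adjusted p = 0.496). Type I interferon genes lay below 0 in 30 of 32 (median log2 -0.82, 0 called, 1 over the list alone, camera adjusted p = 3.562e-08, or 0.541 with an estimated correlation), with Ifit3 at 5.90 ± 3.43 against 33.8 ± 14.9 (adjusted p = 0.866). T cell genes had a median of log2 -1.80 (0 of 15 above 0, 0 called, 0 over the list alone). By camera these genes had adjusted p = 2.093e-07, or 0.664 with an estimated correlation. Aged mouse 3 held 20.7% and young mouse 2 64.5% of the node's own profile. Without young 2 the interferon median was log2 -0.53 (camera adjusted p = 1.083e-05). Without aged 3 there were 10 calls.

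In the lung, the joining chain of secreted antibodies rose with age, and genes of MHC class II presentation and of motile cilia, which clear mucus from the airways, stood higher. With limma, 1 gene was called among 15312 (1386 with unadjusted p under 0.05, 540008 to 852458 reads in aged and 620412 to 953013 in young libraries): Jchain (NM_152839) rose from 5.19 ± 1.08 to 100.3 ± 39.5 (log2 4.21, SE 0.345, adjusted p = 0.00129). MHC class II presentation genes had a median of log2 1.19 (9 of 10 above 0, 0 called, 9 over the list alone). For this group camera gave adjusted p = 3.090e-06, or 0.583 with an estimated correlation. Cilia genes had a median of log2 1.12 (14 of 15 above 0, 0 called, 5 over the list alone). Camera tested the list at adjusted p = 3.090e-06, or 0.583 with an estimated correlation. Collagens and other fibroblast genes, which build the matrix, had a median of log2 -0.33 (0 called, 3 over the list alone, camera adjusted p = 0.00618, or 0.583 with an estimated correlation), with Col3a1, the collagen of distensible tissue, at log2 -1.79 (adjusted p = 0.279). Pisd-ps2 (log2 2.53, adjusted p = 0.117) and A2ml1 (log2 2.39, adjusted p = 0.117) did not pass. The library of young mouse 2 held 62.6% of liver profile. Without it the cilia median was log2 0.52 (camera adjusted p = 1.506e-04) and 16 genes were called, without aged 2 there were 0, and without young 3 there were 2.

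In the colon, Vsig2, a surface protein of the gut epithelium, Apob, the scaffold of the particles that carry dietary fat, and Gstm1, which detoxifies electrophiles, rose with age. Lypd8, which keeps bacteria away from the colonic epithelium, rose as well, and Meg3, a maternally expressed noncoding RNA, fell. With limma 5 genes were higher and 1 lower among 14921 (1461 with unadjusted p under 0.05, 670030 to 798778 reads in aged and 415539 to 614567 in young libraries). Apob (NM_009693) rose from 11.5 ± 1.29 to 52.1 ± 6.34 (log2 2.18, SE 0.265, adjusted p = 0.00585). Vsig2 rose by log2 3.06 (adjusted p = 0.012), Gstm1 by 1.17 (adjusted p = 0.0209), Rps29 by 1.17 (adjusted p = 0.0463) and Lypd8 by 1.02 (adjusted p = 0.0394), and Meg3 (NR_027652) fell by 2.28 on the log2 scale (adjusted p = 0.0109). Genes of the cell cycle, which serve the renewal of the crypts, had a median of log2 -0.26 (0 called, 1 over the list alone). By camera these genes had adjusted p = 0.0278, or 0.578 with an estimated correlation. Without young 1 there were 0 calls, without young 2 there were 3 and without aged 3 there were 9.

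In the liver, Slco1a1 (NM_013797), an organic anion transporter, was listed at 0 in both aged libraries and stood at 101.1, 40.3 and 141.3 in young mice. It was the only gene that limma called among 14698 (adjusted p = 0.00136; 579 with unadjusted p under 0.05, voom 0, quantile normalization 3 higher and 22 lower), at 1006003 to 1134770 reads in aged and 734081 to 916759 in young libraries. Saa2 and Saa1, acute phase proteins that the liver secretes in inflammation, were at log2 4.75 (adjusted p = 0.0871) and 4.24 (adjusted p = 0.155). Macrophage genes had a median of log2 1.32 (17 of 18 above 0, 0 called, 1 over the list alone, camera adjusted p = 7.133e-06, or 0.907 with an estimated correlation), with Fcer1g, an adaptor of antibody receptors, at log2 1.87 (adjusted p = 0.999). The library of young mouse 2 held 37.8% of thymus profile. Without it 3 genes were called, and without young 1 or young 3 there were 0. The median of all genes was log2 0.11, and 0.07 after quantile normalization.

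In bone marrow, B cell genes stood lower and plasma cell genes higher, but limma called 0 of 14219 genes (910 with unadjusted p under 0.05, smallest adjusted p 0.288, voom 0, limma without trend 178), at 616875 to 1077499 reads in aged and 319339 to 574198 in young libraries. Cd79a, a signalling chain of the B cell receptor, was at 56.2 ± 13.4 (n = 3) against 120.5 ± 19.9 (n = 2; limma adjusted p = 0.754). Ccl5, a chemokine of effector T cells, was at 94.8 ± 10.8 against 35.4 ± 3.93 (adjusted p = 0.288) and Jchain at log2 1.51 (adjusted p = 0.288). B cell genes lay below 0 in 13 of 13 (median log2 -0.85, 0 called, 5 over the list alone, camera adjusted p = 8.411e-08, or 0.808 with an estimated correlation), and plasma cell genes had a median of log2 0.96 (9 of 11 above 0, 0 called, 3 over the list alone). For this group camera gave adjusted p = 0.00187, or 0.808 with an estimated correlation. Without young 2 the B cell list was not called (median log2 -0.70, camera adjusted p = 0.0623). Without young 3 there were 215 calls, with a lone young library assumed to vary like the others.

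In the hippocampus the library of young mouse 2 held 61.2% of lymph node profile and 34.3% of its own, so the list medians rest in part on that library. Limma called 0 of 14885 genes (483 with unadjusted p under 0.05, smallest adjusted p 0.896, voom 0, limma without trend 56), at 435422 to 618068 reads in aged and 335953 to 471228 in young libraries. Oligodendrocyte genes had a median of log2 0.72 (12 of 14 above 0, 0 called, 1 over the list alone, camera adjusted p = 1.457e-04, or 0.671 with an estimated correlation), led by Gjb1, a gap junction protein of myelin (log2 1.57, adjusted p = 0.896). Pisd-ps1 and Pisd-ps3 stood at 138.3 ± 7.96 against 51.3 ± 4.83 (log2 1.43, adjusted p = 0.896). MHC class II genes had a median of log2 -2.15 (0 called, 0 over the list alone, camera adjusted p = 0.00173, or 0.671 with an estimated correlation), and their young values rest on young mouse 2, with H2-Aa at 916.9 against 10.8 and 4.85. Without that library the medians were log2 0.30 for oligodendrocyte genes (camera adjusted p = 8.235e-04) and -0.24 for MHC class II genes (camera adjusted p = 0.76), and 4 genes were called. The median of all genes was log2 0.16, and 0.12 after quantile normalization.

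C130026I21Rik was the only gene called in 3 tissues (cervical and mesenteric lymph nodes and spleen), and Sncg, called in choroid plexus and thymus, the only other called in 2 or more. Shuffling gene names within each tissue gave a mean of 0.161 genes in 2 or more tissues and at most 3, and a mean of 4.000e-04 in 3 or more tissues and at most 1. The shuffles treat tissues as independent, but all 11 came from the same 6 mice, so a difference between those mice would repeat across tissues. C130026I21Rik had an unadjusted p under 0.05 in 8 of the 10 tissues where it was tested, all of them higher.

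In parabionts, old against young isochronic animals gave the age effect in choroid plexus a second time. Interferon genes again made up the main group of the higher genes: Ifit1 and Usp18 rose, with Apol9b, an apolipoprotein induced by interferon, Rtp4, Samd9l, which shuts down translation in infected cells, Ifi27l2a and Ifitm3. Tlx2 and the Pisd pseudogenes rose again, with Prom2, an organiser of membrane protrusions, and Sytl1, an effector of vesicle docking. Ccnd2 fell.

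With limma 12 genes were higher and 1 lower among 16504 tested (783 with unadjusted p under 0.05). Ifit1 (NM_008331) rose from 13.4 ± 6.98 to 71.8 ± 14.0 (log2 2.53, SE 0.322, adjusted p = 5.849e-04, n = 3 in each group), and Usp18 (NM_011909) from 11.9 ± 2.35 to 52.7 ± 5.22 (log2 2.15, adjusted p = 5.849e-04). Apol9b rose by log2 2.10 (adjusted p = 0.0475), Prom2 by 1.83 (adjusted p = 0.00649), Rtp4 by 1.82 (adjusted p = 0.00223), Sytl1 by 1.72 (adjusted p = 0.0172), Samd9l by 1.29 (adjusted p = 0.0475) and Ifi27l2a by 1.27 (adjusted p = 5.849e-04). Tlx2 (NM_009392) rose from 28.0 ± 5.16 to 81.1 ± 8.84 (log2 1.55, adjusted p = 7.979e-04), Pisd-ps1 and Pisd-ps3 by log2 0.92 (adjusted p = 7.973e-04) and Ifitm3 by log2 0.49 (adjusted p = 0.0475). Ccnd2 (NM_009829) fell from 270.3 ± 6.53 to 188.4 ± 7.66 (log2 -0.52, SE 0.084, adjusted p = 0.00701). Isg15 (log2 1.69, adjusted p = 0.0546), Irf7 (log2 1.59, adjusted p = 0.0602), Ifit3 (log2 1.34, adjusted p = 0.371) and Oasl2 (log2 1.60, adjusted p = 0.662) did not pass, nor did Evl, a regulator of actin (log2 -1.32, adjusted p = 0.0546), and Ndn (adjusted p = 0.0686).

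Of 30 type I interferon genes 28 lay above 0 (median log2 1.04, 5 called, 21 over the list alone, camera adjusted p = 5.753e-37, or 0.104 with an estimated correlation; fry 0.0445). The interferon score was 4.42 ± 0.241 in old and 3.41 ± 0.289 in young isochronic animals (n = 3 in each; exact permutation p = 0.1, the smallest possible). MHC class I genes had a median of log2 0.16 (0 called, 1 over the list alone). Camera tested the list at adjusted p = 0.00849, or 0.146 with an estimated correlation. Smooth muscle and pericyte genes, which give vessels their tone, had a median of log2 -0.33 (0 called, 3 over the list alone, camera adjusted p = 9.621e-06, or 0.119 with an estimated correlation), with Des, the intermediate filament of muscle, at log2 -0.64 (adjusted p = 0.488). Endothelial genes, of the vessel lining, had a median of log2 -0.25 (0 called, 1 over the list alone). By camera these genes had adjusted p = 3.276e-05, or 0.277 with an estimated correlation. Neutrophil genes had a median of log2 0.82 (0 called, 0 over the list alone). For this group camera gave adjusted p = 0.00228, or 0.119 with an estimated correlation. Libraries did not overlap for 1657 genes (10%, the share by chance). A fit of only the 2 groups called 28 genes, and without old isochronic 23 there were 7.

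**Figure D3:**
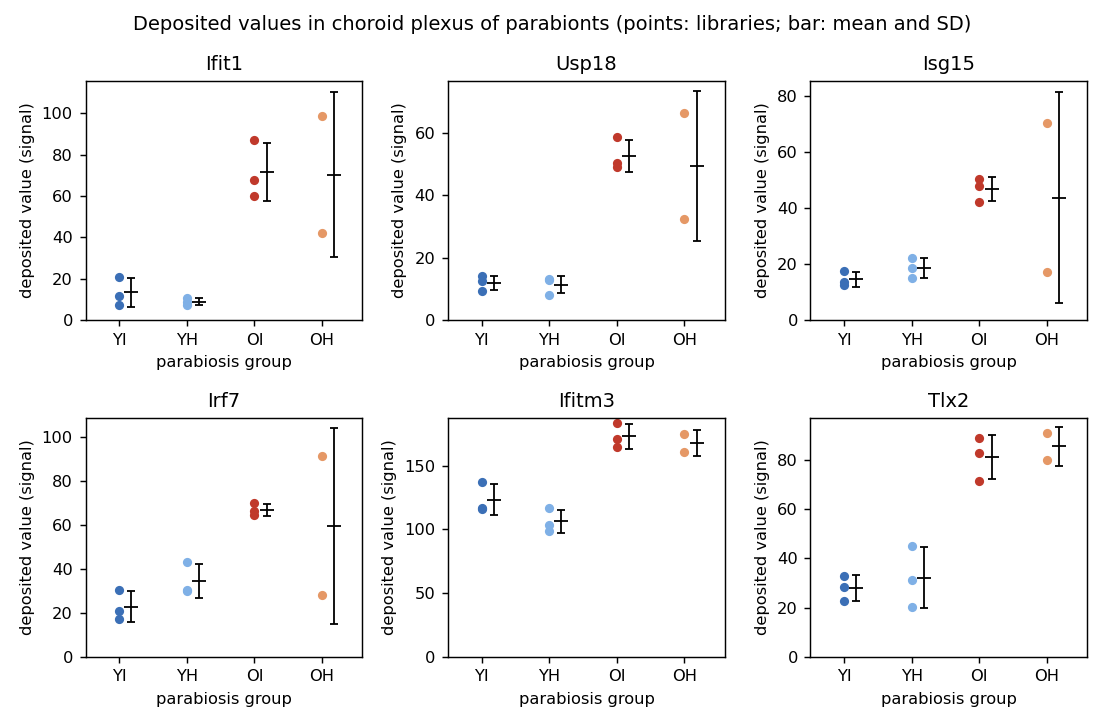
Deposited value (signal, vertical axis) of 6 genes by parabiosis group (horizontal axis), with a point per choroid plexus library and bars for mean and SD, where YI and OI are young and old isochronic and YH and OH young and old heterochronic animals. Ifit1 stands at a mean of 71.8 in old and 13.4 in young isochronic animals, and the 2 old heterochronic libraries lie apart at 98.8 and 42.1.

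Young heterochronic against young isochronic animals asked what an old partner does to a young choroid plexus. Genes of respiration and of the ribosome, for energy and protein supply, stood slightly higher. Heterochronic depth ran lower and was not tested as a cause. Genes of macrophages, pericytes and antigen presentation stood lower. Interferon genes had no common direction. Limma called 0 of 16504 genes (1022 with unadjusted p under 0.05, smallest adjusted p 0.414, voom 0, limma without trend 14). Cx3cr1 (NM_009987), the fractalkine receptor of microglia and resident macrophages, was at 29.1 ± 7.48 against 57.3 ± 8.76 (adjusted p = 0.414, n = 3 in each group). Mag, a myelin adhesion protein, was listed at 0 in the 3 heterochronic libraries and at 9.28, 1.57 and 2.48 in the isochronic ones (adjusted p = 0.414), Podxl, which coats vessel lining and podocytes, was at log2 -0.62 (adjusted p = 0.414), and Steap4, an iron reductase, at log2 -0.98 (adjusted p = 0.674). Atp5k, a subunit of ATP synthase, was at log2 0.44 (adjusted p = 0.674), Ift20, which carries cargo into cilia, at log2 0.39 (adjusted p = 0.708) and Ndufa4, of cytochrome oxidase, at log2 0.32 (adjusted p = 0.708). Irf7 was at log2 0.62 (adjusted p = 0.813), Ifit1 at log2 -0.47 (adjusted p = 0.862) and Isg15 at log2 0.35 (adjusted p = 0.925).

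Oxidative phosphorylation genes lay above 0 in 27 of 28 (median log2 0.14, 0 called, 1 over the list alone, camera adjusted p = 1.255e-11, or 0.381 with an estimated correlation) and ribosomal protein genes in 28 of 30 (median log2 0.09, 0 called, 0 over the list alone). Camera gave adjusted p = 7.157e-05 (0.459 with an estimated correlation). Macrophage genes lay below 0 in 17 of 18 (median log2 -0.57, 0 called, 3 over the list alone, camera adjusted p = 2.410e-06, or 0.359 with an estimated correlation), with Trem2, a lipid sensor of microglia, at log2 -1.38 (adjusted p = 0.674). Smooth muscle and pericyte genes lay below 0 in 10 of 10 (median log2 -0.54, 0 called, 6 over the list alone, camera adjusted p = 1.627e-07, or 0.119 with an estimated correlation), and MHC class II genes had a median of log2 -0.63 (0 called, 0 over the list alone, camera adjusted p = 0.00278, or 0.414 with an estimated correlation). Type I interferon genes were above 0 in 13 and below in 17 (median log2 -0.08, camera adjusted p = 0.208, or 0.796 with an estimated correlation). The interferon score differed by -0.32 (exact permutation p = 0.3, n = 3 in each). Without young heterochronic 11 there were 6 calls, and 1612 genes (9.77%) did not overlap, near the 10% by chance.

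Old heterochronic against old isochronic animals asked what a young partner does to an old choroid plexus. Genes of the choroid plexus epithelium stood slightly higher, among them Enpp2, which makes lysophosphatidic acid, and Folr1, the folate receptor that carries the vitamin into the cerebrospinal fluid. With 2 libraries against 3, limma called 0 of 16504 genes (1414 with unadjusted p under 0.05, smallest adjusted p 0.115, voom 0, limma without trend 50). Enpp2 was at 834.4 ± 145.8 (n = 2) against 607.8 ± 40.2 (n = 3; limma adjusted p = 0.306), and Cst3, a protease inhibitor secreted into the fluid, at log2 0.37 (adjusted p = 0.332). Tuba1a, a tubulin of growing cells, was at log2 0.46 (adjusted p = 0.257), Cadm2, an adhesion protein, at log2 0.57 (adjusted p = 0.291) and Mepce, which caps small RNA, at log2 0.44 (adjusted p = 0.291). Rasd1, a Ras protein induced by glucocorticoids, was listed at 0 in both old heterochronic libraries and at 3.85, 2.56 and 3.64 in the isochronic ones (adjusted p = 0.115). 1700013F07Rik was at log2 -1.63 (adjusted p = 0.166) and Trmt10c, a mitochondrial tRNA methyltransferase, at log2 -1.19 (adjusted p = 0.166). Irf7 stood at 91.1 and 28.1 in the 2 old heterochronic libraries against 66.9 ± 2.73 (n = 3), and Isg15 at 70.4 and 17.0 against 46.8 ± 4.18.

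Choroid plexus epithelium genes lay above 0 in 20 of 20 (median log2 0.23, 0 called, 8 over the list alone, camera adjusted p = 1.291e-12, or 0.848 with an estimated correlation). Oxidative phosphorylation genes had a median of log2 0.14 (21 of 28 above 0, 0 called, 0 over the list alone, camera adjusted p = 3.133e-06, or 0.848 with an estimated correlation) and ribosomal protein genes of log2 0.15 (27 of 30 above 0, 0 called, 0 over the list alone, camera adjusted p = 7.896e-06, or 0.848 with an estimated correlation). Type I interferon genes had a median of log2 -0.24 (10 above and 20 below 0, 0 called, 0 over the list alone, camera adjusted p = 0.473, or 0.848 with an estimated correlation), and the interferon score differed by -0.25, with the 2 heterochronic libraries at 4.88 and 3.46 (exact permutation p = 0.8). Without old heterochronic 29 there were 139 calls (135 lower) and without 34 there were 30 (29 lower), each time with a lone library assumed to vary like the others. 4161 genes (25.2%) did not overlap, against 20% by chance.

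Old against young heterochronic animals gave the age effect between animals that each had a partner of the other age. Ifit1, Usp18 and Ifitm3 of the interferon response were among the higher genes, beside Tlx2, Prom2 and the Pisd family. Ndn fell, with Bex4, an adaptor of the neurotrophin receptor family. With limma 9 genes were higher and 6 lower among 16504 (1365 with unadjusted p under 0.05). Ifit1 (NM_008331) stood at 98.8 and 42.1 in old against 8.92 ± 1.65 (n = 3) in young animals (log2 2.86, SE 0.359, limma adjusted p = 0.00144), and 1700030C10Rik (NR_015521) rose by log2 3.70 (adjusted p = 0.00543). Prom2 rose by log2 2.46 (adjusted p = 0.00179), Usp18 by 2.06 (adjusted p = 0.0027), Tlx2 by 1.48 (adjusted p = 0.0064), Pisd-ps1 and Pisd-ps3 by 0.95 (adjusted p = 0.0027), Pisd by 0.67 (adjusted p = 0.03) and Ifitm3 by 0.66 (adjusted p = 0.0064). Ndn (NM_010882) fell by 1.21 on the log2 scale (adjusted p = 0.0378), Bex4 by log2 -2.09 (adjusted p = 0.0432) and 9930104L06Rik by log2 -2.88 (adjusted p = 0.0212). Rasd1 and Crip3 were listed at 0 in both old libraries and stood between 2.32 and 5.03 in the young ones (adjusted p = 0.0123 and 0.0378). Irf7 (log2 0.58, adjusted p = 0.682) and Isg15 (log2 0.92, adjusted p = 0.505) did not pass.

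Type I interferon genes lay above 0 in 29 of 30 (median log2 0.92, 3 called, 16 over the list alone, camera adjusted p = 1.519e-22, or 0.184 with an estimated correlation). MHC class I genes had a median of log2 0.31 (0 called, 2 over the list alone, camera adjusted p = 2.896e-05, or 0.0663 with an estimated correlation). MHC class II genes had one of log2 0.87 (0 called, 3 over the list alone, camera adjusted p = 3.752e-05, or 0.346 with an estimated correlation). Macrophage genes, of the resident immune cells, had one of log2 0.63 (0 called, 2 over the list alone, camera adjusted p = 1.790e-04, or 0.311 with an estimated correlation). Without old heterochronic 29 there were 127 calls, 9 higher and the rest lower, and without 34 there were 64, 17 higher and 47 lower, with a lone library assumed to vary like the others. Without young heterochronic 14 there were 10, and a fit of only the 2 groups gave 4.

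The last parabiosis comparison asked if the heterochronic effect in young animals differed from that in old ones. No gene passed: limma called 0 of 16504 (1001 with unadjusted p under 0.05, smallest adjusted p 0.513, voom 0, limma without trend 30). Rps10, a ribosomal protein, was at log2 0.69 (SE 0.144, adjusted p = 0.513), 1700013F07Rik at 2.03 (adjusted p = 0.513), Cx3cr1 at -1.31 (adjusted p = 0.619) and Ahnak, a giant scaffold protein, at -0.63 (adjusted p = 0.619). MHC class II genes had a median of log2 -1.03 (0 called, 2 over the list alone, camera adjusted p = 3.380e-04, or 0.441 with an estimated correlation) and macrophage genes of log2 -0.66 (0 called, 4 over the list alone, camera adjusted p = 1.018e-04, or 0.441 with an estimated correlation). Without old heterochronic 29 there were 29 calls and without 34 there were 5.

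Both experiments measured the age effect in choroid plexus on separate libraries, of opposite sex by sex-linked genes. In both, 8 genes were called, all 8 in the same direction, where 0.025 would be if the lists were independent. They were Ifit1, Rtp4, Ifi27l2a and Ifitm3 of the interferon response, Tlx2, the cyclin Ccnd2, and Pisd-ps1 and Pisd-ps3, 1 shared signal counted as 2 genes. Of the 26 genes called in tissues 23 kept direction in isochronic parabionts, and of the 13 called there 12 did in tissues. Across all 13643 genes tested in both, the log2 changes had a Pearson r of 0.0755 and a Spearman rho of 0.0746; genes are not independent replicates. In the upper part of mean expression (6131 genes) r was 0.133, and over the 26 called in tissues it was 0.671.

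**Figure D4:**
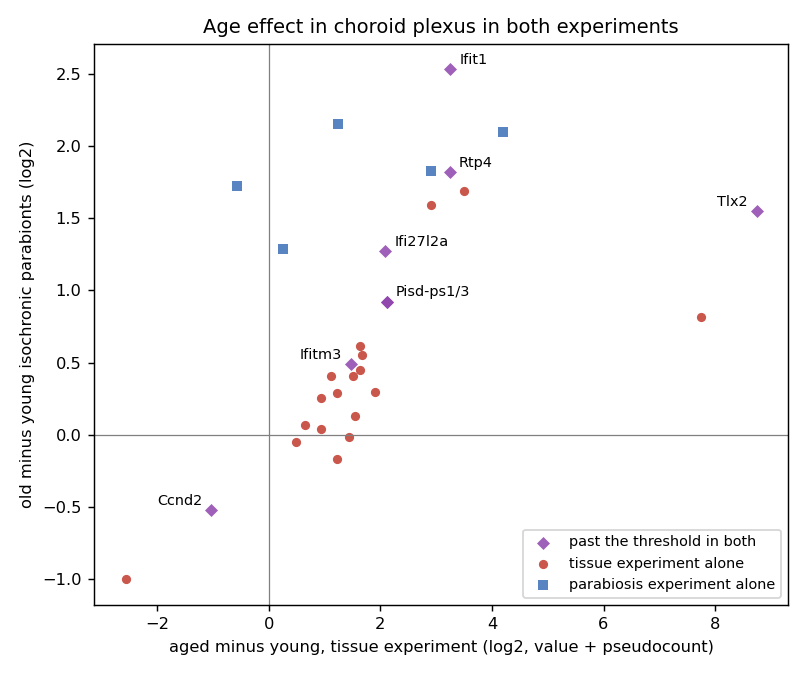
Log2 change with age in choroid plexus in the tissue experiment (horizontal axis) and in isochronic parabionts (vertical axis), one point per gene called in either experiment and tested in both, with shapes for called in both or in one alone. The 8 genes called in both lie in matching directions, and the horizontal position of Tlx2 depends on the pseudocount because young choroid plexus was listed at 0.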

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

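The second-organ tests, the mislabelling test with the bound it used, the macrophage test and the split test with a 1-read pseudocount were chosen only after the result was seen, and so was the bootstrap bound on the matched random lists.

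The age effect in choroid plexus differed from the mean of the other 10 tissues in 315 genes. Of the 9 other splits of the mice 3 gave as many (highest 364), so the count is not specific to age. Also, 10 splits are too few for a share under 0.05. With a 1-read pseudocount and filter 23 genes differed, and the highest other split gave 5. Among the 315 were Isg15 at log2 3.19 and Ifit1 at 2.99, of the interferon response, which voom did not call. Pisd stood at 1.06, Pisd-ps1 and Pisd-ps3, which share reads, at 1.76, and Sult1c1 at 7.87 and Tlx2 at 9.71, fitted values that depend on the pseudocount. The age difference of the interferon score in choroid plexus exceeded that in inguinal lymph nodes by 2.87 and that in bone marrow by 1.914 (exact p = 0.005 and 0.035, 0.05 and 0.119 adjusted over 10 tissues). These p-values treat tissues of one mouse as independent and do not test equal age effects. In inguinal lymph nodes aged mouse 3 and young mouse 2 held 20.7% and 64.5% of the own profile. The first difference thus also carries composition. Without young mouse 2 in the other tissue the differences were 2.74 and 1.77 (0.1 and 0.143 adjusted).

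The first pattern weighed is the second organ in young mouse 2, whose share exceeded that of every other library of the tissue in 8 of 11 tissues, narrowly in inguinal lymph nodes (31.4% against 28.8%). RNA or reads of a second organ in the library may account for it. A swap of whole labels was argued against by the own-organ share, which was 14.5% in the lowest of these libraries (spleen), where lung libraries of the other mice held at most 8.1% of spleen. At which step a second organ entered, in dissection, library preparation or read assignment, was not tested, and no biological explanation was tested. The choroid plexus library of this mouse held 1.6% of its largest second organ.

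The second pattern is the rise of abundant gene lists in old heterochronic against old isochronic animals, whose libraries differ in depth (534663 to 687909 against 799608 to 886349 reads). Random lists matched on mean expression test depth and the compression of high values. Oxidative phosphorylation genes lay inside the random range, at percentile 59 (median log2 0.144, random 0.0971 to 0.187), so depth could account for them. Ribosomal protein genes lay above it, at percentile 100 (0.149, random -0.0203 to 0.107, bootstrap 0.11 to 0.195). Choroid plexus epithelium genes were at percentile 97.9 (0.227, random up to 0.226), but their bootstrap interval of 0.178 to 0.318 reached into that range, so depth and an effect of the young partner cannot be told apart. Without the bootstrap bound this list would have counted against depth.

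The third pattern is the rise of type I interferon genes in aged choroid plexus in both experiments. Depth was argued against by matched random lists, with percentile 100 in both (2.02, random -0.316 to 0.358, and 1.04, random -0.109 to 0.0997). More macrophages, as the whole cause, were argued against by the macrophage list, whose median was lower by 0.872 in tissues (interval 0.0278 to 1.8) and by 1.23 in isochronic parabionts (interval 0.626 to 1.86), where it was -0.195. Intervals are over genes, not mice, the first ends near 0, and macrophages may contribute. An interferon response with age may be a candidate explanation, as a hypothesis found and tested on these libraries.

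For the counts of calls with 3 libraries against 3, 10 splits are too few for a share under 0.05. The real split called 26 genes in choroid plexus, 48 in thymus, 11 in spleen, 6 in colon, 1 in lung and 1 in mesenteric lymph nodes, and 13 in old against young isochronic parabionts, with 0 in the highest other split of each. In hippocampus, inguinal lymph nodes and young heterochronic against young isochronic animals limma called 0 in each of the 10 splits, where 483, 591 and 1022 genes had an unadjusted p under 0.05 in the real one and voom called 0.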

How the results depend on the processing

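Fits with a 1-read pseudocount and filter, with voom or without young mouse 2 were chosen after seeing the data. So were list tests and between-tissue scores without that mouse and the leave-one-out correlation. Of 2323 alternative values over 165 pairs of gene and comparison, 220 lost significance, 63 gained it and 0 reversed among called values. The other 2040 include genes that stayed uncalled and do not show how stable calls are. Depth of 187827 to 1134770 reads limits claims on genes near the pseudocount.

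Limma without trend called 112 genes in choroid plexus, 178 in bone marrow, 139 in cervical lymph nodes, 90 in colon, 56 in hippocampus, 53 in inguinal lymph nodes, 87 in liver, 63 in lung, 91 in mesenteric lymph nodes, 78 in spleen and 97 in thymus. In parabionts it called 21 for old against young isochronic, 14 for young heterochronic against isochronic, 50 for old heterochronic against isochronic, 45 for old against young heterochronic and 30 for the difference of heterochronic effects. The cause was not tested.

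With no filter on low values there were 52 calls in choroid plexus, 6 in cervical lymph nodes, 2 in liver, 2 in mesenteric lymph nodes and 18 in spleen, with more genes tested. With the 1-read pseudocount and filter there were 5 in bone marrow, 32 in cervical lymph nodes, 14 in colon, 2 in liver, 4 in mesenteric lymph nodes, 18 in spleen, 125 in thymus, 23 for choroid plexus against the other tissues and 25 for old against young isochronic parabionts. Voom called 17 in colon, 0 in liver, 0 in mesenteric lymph nodes, 127 in thymus, 13 for choroid plexus against the other tissues and 20 for old against young isochronic parabionts. Beside those zeros, 579 genes in liver (3.94% of those tested, below the share expected by chance) and 1150 in mesenteric lymph nodes (7.91%) had an unadjusted p under 0.05 by limma. Quantile normalization gave 25 in liver, 2 in mesenteric lymph nodes and 20 for old against young isochronic parabionts. A pseudocount 4 times as large gave 2 in mesenteric lymph nodes and 18 in spleen. A fit of only the 2 groups called 28 for old against young isochronic and 4 for old against young heterochronic parabionts. The cause was not tested.

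Replicate numbers are shared by aged and young mice without pairing them. As a block they gave 0 calls in cervical lymph nodes, 3 in colon, 22 in liver and 91 in thymus, and the cause was not tested. Correlations of the deviations from the group mean between libraries with the same number ran from -0.19 in inguinal lymph nodes to 0.15 in liver, and in thymus 3 of 3 aged libraries were closest to their own number.

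Leaving out 1 library at a time gave ranges of calls of 8 to 22 in choroid plexus, 0 to 215 in bone marrow, 0 to 1351 in cervical lymph nodes, 0 to 9 in colon, 0 to 4 in hippocampus, 0 to 10 in inguinal lymph nodes, 0 to 3 in liver, 0 to 16 in lung, 1 to 5 in mesenteric lymph nodes, 2 to 36 in spleen and 3 to 163 in thymus. In parabionts they were 7 to 12 for old against young isochronic, 0 to 6 for young heterochronic against isochronic, 0 to 139 for old heterochronic against isochronic, 10 to 127 for old against young heterochronic and 0 to 29 for the difference of heterochronic effects. Fewer libraries lower the power, and a lone library is assumed to vary like the others.

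With an estimated correlation camera called 0 lists in each of the 17 comparisons, and none in tissues without young replicate 2. Fry called 2 in choroid plexus, 1 in inguinal lymph nodes, 2 in mesenteric lymph nodes, 2 in spleen, 4 in thymus, 2 for old against young isochronic, 1 for old against young heterochronic parabionts and 0 elsewhere. Both allow for correlation between genes, which the preset value of 0.01 largely leaves out. Without young replicate 2, camera called 8 lists in cervical lymph nodes instead of 22, 13 in colon instead of 8, 8 in hippocampus instead of 16 and 14 in mesenteric lymph nodes instead of 23.

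The sign of a small age difference in interferon score depended on the setting. In bone marrow (-0.057) the median over genes gave 0.0317, the list without 3 of its genes 0.0476, and leaving out libraries -0.205 to 0.0913. In hippocampus (-0.447) the median gave 0.0126 and leaving out libraries -1.358 to 1.21. In thymus (-0.0055) the median gave 0.0872, the shorter list 0.0169, and leaving out libraries -0.265 to 0.261. Leaving out libraries gave -0.227 to 0.799 in liver, -0.0312 to 0.569 in mesenteric lymph nodes, -0.0363 to 0.161 in spleen and -0.958 to 0.467 for old heterochronic against isochronic animals. The cause was not tested.

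The correlation of age effects between both experiments (0.0755) was 0.133 in the upper part of mean expression and 0.0443 to 0.0806 leaving out 1 library at a time. Of genes called in several tissues, 2 were called in 2 or more and 0 in 4 or more, by the construction of the count.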

Other observations

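The genes in the first 2 paragraphs were chosen after their values were seen, and the tests of both heterochronic hypotheses were chosen only after the result was seen.

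Oasl2, an antiviral member of the OAS family, lay above 0 with age in 11 of 11 tissues, with an unadjusted p under 0.05 in 6 and a median of log2 0.84, though it was called in none. C4b, a complement factor made by liver and glia, lay above 0 in 10 of 11 tissues, with 6 at an unadjusted p under 0.05. Wfdc17, a protein of activated macrophages, lay above 0 in 10 of 10 tissues, with 6 at an unadjusted p under 0.05 and a median of log2 1.87. Jchain and Mzb1, of antibody-secreting cells, each lay above 0 in 9 of 11 tissues, with 7 and 4 at an unadjusted p under 0.05, and each lay below 0 at an unadjusted p under 0.05 in 1 tissue.

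In spleen, erythroid genes, which build haemoglobin and the red cell membrane, lay above 0 in 15 of 15 (median log2 1.87, camera adjusted p = 5.741e-06, adjusted p = 0.672 with an estimated correlation). Without the library of young mouse 2, which held 14.5% of spleen profile, the median was log2 0.63 (camera adjusted p = 0.0335). Cell cycle genes lay above 0 in 21 of 22 there (median log2 0.97, camera adjusted p = 1.442e-07, adjusted p = 0.672 with an estimated correlation), and without that library the median was log2 0.5 (camera adjusted p = 0.00241). In thymus, complement genes had a median of log2 0.86 (0 called, 6 adjusted over the list alone, camera adjusted p = 9.097e-05, adjusted p = 0.438 with an estimated correlation), and 1.39 without the young mouse 2 library (camera adjusted p = 3.941e-08). In inguinal lymph nodes clock genes had a median of log2 1.0 (0 called, 2 adjusted over the list alone, camera adjusted p = 2.477e-04, adjusted p = 0.541 with an estimated correlation). In cervical lymph nodes genes of natural killer and cytotoxic cells, which lyse infected cells, had a median of log2 0.91 (0 called, 6 adjusted over the list alone, camera adjusted p = 3.897e-04, adjusted p = 0.44 with an estimated correlation). Without young mouse 2, whose library held 34.0% of hippocampus profile, that median was log2 0.199 (camera adjusted p = 0.043).

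The 24 genes called higher with age in choroid plexus of the tissue experiment were followed through the parabionts. Their median was log2 0.47 in old against young isochronic and 0.55 in old against young heterochronic animals, above random lists matched on mean expression in both (percentile 100). A first hypothesis was that an old partner raises them in young animals. Their median was log2 0.06, at percentile 78.7 of the matched lists, inside the random range of -0.0235 to 0.0882. A second hypothesis was that a young partner lowers them in old animals. Their median was log2 0.06, at percentile 61.1, inside the random range of -0.0353 to 0.124. Both tests came out negative, with 3 libraries against 3 and 2 against 3.

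Parabiosis values had a flatter range than tissue values. Ttr had 848 to 993 reads in parabionts against 170131 to 222839 in choroid plexus of the tissue experiment. The ratio of median reads, parabiosis to tissue, was 5.01 for genes of 2 to 8 tissue reads and 0.425 for the 56 genes in the highest range.

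The X-linked Xist stood at 26.4 to 112.5 and the Y-linked Ddx3y at 0 to 1.4 in the tissue libraries. In the parabionts Xist stood at 0 to 1.9 and Ddx3y at 157.2 to 196.6.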
